A study of Mus musculus with 24 samples.

How the data were processed

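RNA was sequenced from mouse embryonic stem cells in 24 libraries, which the labels place in 8 groups of 3: F/F and KO cells for Lin54, Lin52, Lin37 and Lin9. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with an Illumina TruSeq kit. The tables of the Lin37 and Lin9 lines name their control columns with the letter W and a number; these were taken as the F/F libraries of the same number, since each table holds 1 KO group and 1 other group of 3.

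The authors deposited a table for each line with an estimated count per gene and library, which is an expected count as RSEM gives it and need not be whole; 11.7 to 14.0% of values per library had decimals. The deposited tables also hold the authors' log2 fold change and p-value columns for KO against F/F, which were used only to count how many genes they list as changed. The 32 deposited TPM columns were not used here. The gene length column of the deposited tables was used only in the test of GC content and gene length in Lin9 KO replicate 2. Per the submitters' processing notes, the tools were FastQC, HISAT2 2.1.0, RSEM and DESeq 1.26.0 with genome build GRCm38.p6. The annotation release, the strand setting and the options of RSEM are not given in the sources used here. RSEM shares reads between genes by estimation, so counts of near-identical genes depend on its model. Each table had 55486 rows with a gene and 1 emptied row, which was skipped. Positions came from a GENCODE annotation of GRCm38, which held 55140 of the identifiers; 96.1% of all had the same name there. Where a symbol had 2 rows, the row with more counts was used.

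Estimated counts were rounded to whole numbers. Library totals were 19128769 to 26501071 counts, so genes far below the minimum of 2 counts-per-million used for naming have wide counting error. Each line's 6 libraries were fitted alone in edgeR 4.0.16 (R 4.3.3) with TMM factors, filterByExpr with its defaults, glmQLFit and glmQLFTest, and Benjamini-Hochberg adjustment with a threshold of 0.05. Gene lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01 between members, adjusted over the lists within a line, and again with an estimated correlation. With an estimated correlation the test within a line rests on the few residual degrees of freedom of 6 libraries. A call lost under it may therefore reflect the number of libraries rather than the list. The effect of KO was compared between lines in a fit of all 24 libraries with 8 group means, by an F test of 3 interaction terms. Log2 fold changes were correlated across genes for the 6 pairs of lines. Because the 4 comparisons share no libraries, overlaps were set against those of independent lists. Summaries and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

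The groups, tests, 18 gene lists with 387 genes, the rule for named genes and most alternatives were fixed before the data were examined. The rule names the targeted genes and the MuvB list, and up to 4 members of each list with the smallest p. It also names, per line, the 6 genes highest and the 6 lowest in KO by log2 fold change among called genes with a mean of at least 2 counts-per-million, no overlap between the groups and a symbol that is not a predicted model. The 6 genes with the largest mean change among those called alike in all 4 lines, and the 6 with the smallest interaction p, complete it. A few genes that the rule names are not reported here. Lists cover MuvB subunits, G2/M, G1/S, pluripotency, two-cell-like, germline, endoderm, mesoderm, ectoderm, trophoblast, p53 target, interferon-stimulated, cholesterol synthesis, glycolysis and hypoxia, amino acid stress, imprinted and proteasome genes and fibroblast markers, the last because feeder cells could be present. For a gene with 1 to 3 counts in a group the ratio of normalised sums is given with an exact 95% counting interval, and for a group at 0 a fold against a floor of 3 counts over the group.

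The alternatives were DESeq2's size factors in edgeR, DESeq2 1.42.0 (Wald test), no filter on low counts, a stricter filter of 10 counts in every library of 1 group, all 24 libraries in the fit, the replicate number as a block, each library left out, an absolute log2 fold change of at least 1, and fry for the lists. Library totals with no scaling factor and the leave-one-out values of the correlations were chosen after seeing the data. The list tests without Lin9 KO replicate 2 were planned with the other left-out libraries but singled out after seeing the data. Replicates were compared by a chi-square test of their counts, and no pair agreed within sampling noise (chi-square per degree of freedom 2.11 to 27.79), so each library counted once.

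The scripts were tested on simulated counts drawn from the means and library sizes of each line, with 200 changed genes. Of genes changed 2-fold, 100, 100, 100 and 92% were recovered in the Lin54, Lin52, Lin37 and Lin9 simulations (15462, 15267, 15630 and 15403 genes), and of those changed 1.5-fold 98, 90, 96 and 64%. Of genes changed 1.25-fold, 64, 36, 68 and 6% were recovered. The share of false calls was above the nominal 5%: it was 11.9, 10.9, 10.7 and 5.8% in the first draw, above a limit of 10% that had been set for it in 3 lines. It averaged 8.8, 6.7, 8.6 and 8.6% over 5 further draws with gene-wise dispersions, and 4.4, 3.0, 5.4 and 6.2% with dispersions on the trend. Unadjusted p under 0.05 came up in 4.70 to 5.06% of unchanged genes. The limit was then dropped as a condition, and the test was left as planned, so adjusted p in the text may be somewhat too small where few genes change. The interaction simulation (17246 genes) recovered 98% at 2-fold and 78% at 1.5-fold with 4% false calls. Of 100 random lists per line, 0, 0, 0 and 1 had an unadjusted p under 0.05. Genes were simulated independently of each other, so these lists cannot check the preset correlation used for real lists. The real comparisons called 5097 (Lin9) to 13214 (Lin54) genes, so the simulated shares come from a setting with far fewer changes.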

Results

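RNA sequencing profiles from total RNA were compared between mouse embryonic stem cells of the C57BL/6 strain labelled F/F and cells labelled KO for the same gene. The genes were Lin54, Lin52, Lin37 and Lin9, which encode subunits of MuvB, a complex that binds cell cycle gene promoters and acts with p130 and E2F4 as a repressor (the DREAM complex) or with B-Myb and FoxM1 as an activator. Each of the 4 lines had 3 F/F and 3 KO libraries, giving 24 libraries in 8 groups. Library totals lay between 19128769 and 26501071 estimated counts. Each KO group was compared with the F/F group of its own line, which asked what changed in stem cells when that subunit was targeted. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Levels are TMM-normalised counts-per-million (CPM), given as mean ± SD with n = 3 per group. Fold changes are log2 values of KO over F/F from edgeR's quasi-likelihood test, with its standard error (SE) and Benjamini-Hochberg adjusted p. Genes were named by a rule set beforehand, except the members named because 5 or fewer of a list went another way or because they stood out within a list, which were chosen after their values were seen. Rankings by fold change within a line are among called genes with a mean of at least 2 CPM, no overlap between the groups and a symbol that is not a predicted model. For genes named by such a ranking, no overlap therefore restates the rule. Among all genes tested the groups did not overlap for 81.4, 77.3, 54.1 and 47.3% in the Lin54, Lin52, Lin37 and Lin9 lines. Counting intervals and floors cover counting error only.

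The targeted genes were examined first. Lin37 (ENSMUSG00000036845, chromosome 7, 30555441 to 30559838, minus strand, up to 9 exons in GRCm38) fell in the Lin37 KO libraries from 10.5 ± 0.485 to 3.72 ± 0.143 CPM, a log2 fold change of -1.49 (SE 0.106, adjusted p = 2.58e-08). Lin52 (ENSMUSG00000085793, chromosome 12, 84451422 to 84546145, plus strand, up to 6 exons) was at 7.73 ± 0.101 CPM in F/F and 5.89 ± 1.1 CPM in KO, a log2 fold change of -0.40 (SE 0.141, adjusted p = 0.0246) with all 3 KO libraries below all 3 F/F libraries. That call was lost in DESeq2 (-0.39, adjusted p = 0.0721) and with library totals as the scaling (-0.24, adjusted p = 0.154). It was also lost without Lin52 F/F replicate 1 (adjusted p = 0.0511), replicate 2 (0.051) or replicate 3 (0.0633), and without Lin52 KO replicate 2 (-0.25, adjusted p = 0.0854). Lin9 (ENSMUSG00000058729, chromosome 1, 180641150 to 180690694, plus strand, up to 15 exons) did not differ detectably in its own line, at 22.9 ± 1.95 CPM in F/F and 21.4 ± 1.40 CPM in KO (log2 fold change -0.10, 95% interval -0.27 to 0.07, adjusted p = 0.44). Lin54 (ENSMUSG00000035310, chromosome 5, 100441918 to 100500639, minus strand, up to 14 exons) went against its label, with 28.2 ± 2.04 CPM in the libraries labelled Lin54 F/F and 35.7 ± 2.99 CPM in the libraries labelled Lin54 KO, a log2 fold change of 0.34 (SE 0.0684, adjusted p = 0.000289). Lin37 overlaps Hspb6 on the opposite strand, so its counts may include reads of that gene. The deleted part of each gene is not given in the sources used here, and counts over a whole gene include exons outside it, so these values may check nothing about the deletion.

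**Figure D1:**
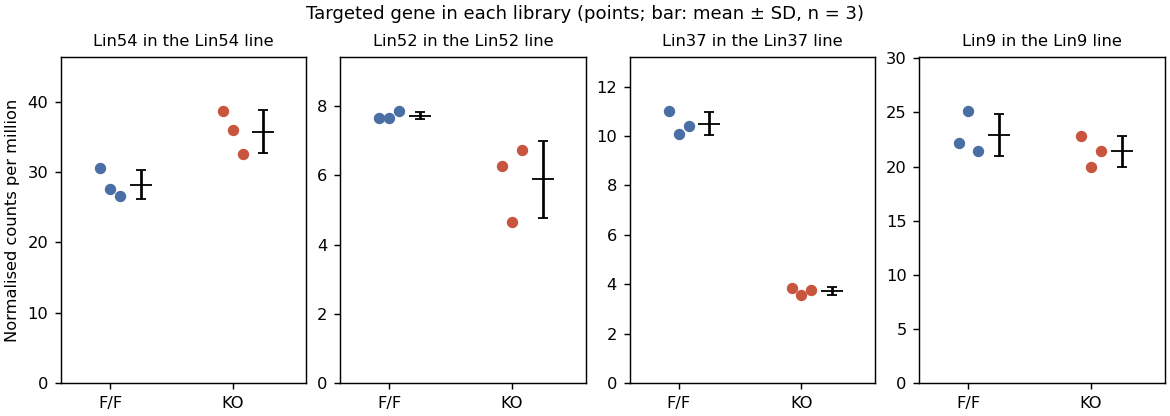
Normalised counts-per-million (linear axes from 0) of Lin54, Lin52, Lin37 and Lin9, each in its own line, with a point for each library and a bar for the mean ± SD of 3 libraries. Lin37 sits at a mean of 10.5 in F/F and 3.72 in KO, while Lin54 sits at 28.2 in F/F and 35.7 in the libraries labelled KO.

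In the Lin54 line, pluripotency, G1/S and cholesterol synthesis genes were lower in the libraries labelled Lin54 KO, and p53 targets were higher. These directions rest on labels that the level of Lin54 itself went against. Nanog, a core pluripotency factor, was at 114 ± 1.95 CPM in F/F and 2.63 ± 0.659 CPM in the libraries labelled KO (log2 fold change -5.42, SE 0.08, adjusted p = 3.23e-17). Among genes with a mean of at least 2 CPM the other largest falls were in Lefty2 (-6.16) and Lefty1 (-4.91), which encode antagonists of Nodal signalling, the homeobox gene Otx2 (-5.28), the neurogenic factor Neurog1 (-5.12) and Trh, which encodes thyrotropin-releasing hormone (-4.82). Among the largest rises were P2rx7, an ATP-gated ion channel gene (5.69, from 4.98 ± 0.102 to 258 ± 18.7 CPM), and Fam83a (7.12). Ppargc1a, a coactivator gene of mitochondrial metabolism, had 1 count in the F/F group and 407 in the other, a ratio of 363 with a 95% counting interval of 64.7 to 14400. Serpinf2 (ratio 100, interval 33.9 to 488), the vomeronasal receptor gene Vmn1r9 (117, 39.6 to 568) and the histocompatibility gene H2-M2 (123, 41.7 to 597) each had 3 counts in F/F. In all of these genes every library labelled KO lay beyond every F/F library, and the highest adjusted p was 4.15e-10.

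Of 24 pluripotency genes, 21 fell in the libraries labelled Lin54 KO (median log2 fold change -1.53), among them Pou5f1 (-2.24, from 864 to 183 CPM), Sox2 (-2.64), Tdgf1 (-3.74) and Fgf4 (-3.24), while Klf5 (0.74) and Tbx3 (0.49) rose. Adjusted over the list alone, 23 were called. Cell cycle genes were lower too. Of 55 G2/M genes 47 fell (median -0.65), with Top2a at -1.78, Ube2c at -2.07, Cenpa at -2.25 and Ccnb1 at -1.32. Of 38 G1/S genes 36 fell (median -0.78), with Msh6 at -1.74, Uhrf1 at -1.62 and Pcna at -1.24. Adjusted over the list alone, 53 G2/M and 38 G1/S genes were called. Each of the 20 cholesterol synthesis genes fell (20 adjusted over the list alone, median -1.1), with Hmgcs1 at -1.87 and Idi1 at -1.98. Of 24 p53 target genes, 19 rose (23 called adjusted over the list alone, median 1.02), including Cdkn1a (2.26), Mdm2 (1.76), Plk2 (2.25) and Perp (2.38). Sesn1 (-1.6), Ei24 (-0.51), Bax (-0.13) and Zmat3 (-0.08) fell, Bax and Zmat3 by less than the shift of 0.24 that library totals add to the median of all genes. Camera, a competitive list test, gave adjusted p = 2.81e-23 for pluripotency, 9.3e-13 for G1/S, 2.96e-13 for cholesterol synthesis and 7.53e-11 for p53 targets. With an estimated correlation between members these 4 calls held, at adjusted p = 0.00584, 0.00857, 0.00913 and 0.00913. The G2/M call (adjusted p = 2.96e-13) was lost, at adjusted p = 0.0731 with an estimated correlation.

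The other lists called in the Lin54 line were lost with an estimated correlation. Germline and meiosis genes were higher (20 of 23 rose, 21 called adjusted over the list alone, adjusted p = 5.67e-05, and 0.052 with an estimated correlation), among them Ddx4 (1.87) and Taf7l (4.04). Of 12 trophoblast genes tested, 8 rose (11 adjusted over the list alone; adjusted p = 0.00187, and 0.194 with an estimated correlation). The keratin genes Krt18, from 149 to 1430 CPM, and Krt8, from 249 to 1610 CPM, were among them and are also expressed in other simple epithelia. Of 19 glycolysis and hypoxia genes 15 fell (19 adjusted over the list alone; adjusted p = 1.55e-06, and 0.194 with an estimated correlation), such as Ldha (-1.84) and Pdk1 (-2.47). Proteasome genes fell in all 14 cases (14 adjusted over the list alone; adjusted p = 0.000113, and 0.196 with an estimated correlation). So did 13 of 18 amino acid stress genes (18 adjusted over the list alone; adjusted p = 0.0118, and 0.105 with an estimated correlation). The stress transcription factor genes Ddit3 (2.71), Atf3 (3.38), Atf4 (0.73), Atf5 (0.94) and Cebpb (0.63) rose instead. Ectoderm and neural genes (9 of 14 fell, 13 adjusted over the list alone; adjusted p = 0.0329, and 0.155 with an estimated correlation) were lower with Tubb3 at -2.78 and Olig2 at -3.49, while Nes rose (1.30). Imprinted genes (11 of 17 fell, 14 adjusted over the list alone; adjusted p = 0.0368, and 0.155 with an estimated correlation) were lower, with Cdkn1c at -1.76 and Mest at -1.14. That call was also lost with the replicate number as a block (adjusted p = 0.0524) and with library totals (0.0635). The lists of MuvB subunits, endoderm, mesoderm, interferon-stimulated genes and fibroblast markers were not called (adjusted p = 0.128, 0.208, 0.117, 0.484 and 0.37). Camera compares a list with the other genes, so members of a list not called can still change. Of 17 endoderm genes tested 11 rose and 3 fell (median 1.07), and of 9 mesoderm genes 6 rose and 0 fell (median 1.315). For fibroblast markers the median (-0.04) and the mean (0.16) differed in sign. Within the MuvB list 6 of 13 members fell, among them Mybl2 (-1.28), Tfdp1 (-0.94) and Tfdp2 (-1.63), and 3 rose, among them Foxm1 (1.12).

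In all, 13214 of 16539 genes tested were called in the Lin54 line, 6725 higher and 6489 lower in the libraries labelled KO, and 5071 had an absolute log2 fold change of at least 1. With library totals in place of TMM the median of all genes shifted by 0.24, and the split became 8516 higher and 4781 lower (64.0% higher against 50.9%). Directions here are therefore relative to the bulk of genes. The mitochondrial share of counts moved with the label, from 2.26 to 2.47% in F/F to 1.00 to 1.18% in the libraries labelled KO. So did the share of the 10 most abundant genes, from 5.90 to 6.02% to 4.34 to 4.51%.

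In the Lin52 KO libraries pluripotency, G2/M and G1/S genes were lower, and p53 targets were higher. Nanog fell from 89.3 ± 0.574 to 2.55 ± 0.43 CPM (-5.13, SE 0.0853, adjusted p = 4.24e-12) and Mycn, a growth-promoting transcription factor gene, from 350 ± 10.1 to 16.9 ± 0.636 CPM (-4.37). The other large falls were in Neurog1 (-5.47), the nephrin gene Nphs1 (-5.19), the ectonucleotidase gene Enpp3 (-4.35) and the forkhead factor gene Foxd3 (-4.31). The largest rises included the skeletal muscle actin gene Acta1 (4.81, from 1.32 to 36.8 CPM), Stmn4 (4.94), the butyrophilin gene Btn1a1 (5.86), Fgd3 (5.98) and the small heat shock protein gene Hspb2 (4.51). Mybpc3, a cardiac myosin-binding protein gene, had 3 counts in F/F and 424 in KO, a ratio of 121 with a counting interval of 41 to 587. Every KO library lay beyond every F/F library for these 12 genes, and their highest adjusted p was 5.43e-08.

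Of 24 pluripotency genes 21 fell in Lin52 KO (24 called adjusted over the list alone, median -1.58), with Sox2 at -2.42 and Tdgf1 at -3.76, while Klf5 (1.07), Tbx3 (1.19) and Klf4 (0.70) rose. G2/M genes fell in 49 of 55 cases (52 adjusted over the list alone, median -0.78), such as Top2a (-2.20), Ccnb1 (-1.75) and Cenpa (-2.14), whereas Anln (0.88), Gtse1 (0.31) and Psrc1 (0.17) rose. G1/S genes fell in 35 of 38 cases (35 adjusted over the list alone, median -0.69), such as Rrm2 (-1.22) and Cdca7 (-1.72). Of 24 p53 target genes 19 rose (20 adjusted over the list alone, median 1.45), with Perp at 2.81, Plk2 at 2.69, Mdm2 at 1.97 and Cdkn1a at 2.39, and Sesn1 fell (-1.47). Camera gave adjusted p = 1.2e-22, 3.41e-18, 2.05e-10 and 1.75e-15 for these 4 lists. With an estimated correlation all 4 held, at adjusted p = 0.0051, 0.0051, 0.0208 and 0.0051.

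Trophoblast genes rose in Lin52 KO in 8 of 12 cases (9 adjusted over the list alone; adjusted p = 2.64e-07, and 0.0624 with an estimated correlation), with Krt18 going from 105 to 2340 CPM and Krt8 from 182 to 2610 CPM. Fgfr2 fell (-0.83). Endoderm genes were higher (11 of 17 rose, 12 adjusted over the list alone; adjusted p = 0.0129, and 0.106 with an estimated correlation), led by the basement membrane collagens Col4a2 (3.25) and Col4a1 (2.57), while the laminin gene Lama1 fell (-2.87). Among fibroblast markers the smooth muscle genes Tagln (3.36) and Acta2 (3.13) rose together with Lox (2.18) and Pdgfrb (1.07). Mmp2 (-1.94) and Thy1 (-0.91) fell, and Col1a1 stood at 0.04 without passing the test. Of 11 markers 6 were called (6 adjusted over the list alone; adjusted p = 0.0326, and 0.129 with an estimated correlation). Without Lin52 F/F replicate 3 that call was lost at adjusted p = 0.0513. Germline genes were higher (15 of 23, 18 adjusted over the list alone; adjusted p = 0.025, and 0.278 with an estimated correlation). Ectoderm genes were lower (7 of 12, 11 adjusted over the list alone; adjusted p = 0.0326, and 0.129 with an estimated correlation). Without Lin52 KO replicate 1, which stood apart from replicates 2 and 3, the germline and ectoderm calls were lost, at adjusted p = 0.0624 and 0.0533. Cholesterol synthesis (16 of 20 fell, 18 adjusted over the list alone), glycolysis and hypoxia (16 of 19, 19 adjusted over the list alone) and amino acid stress genes (13 of 18, 18 adjusted over the list alone) were lower. Dhcr7 was at -1.90, Pdk1 at -2.61 and Mthfd2 at -2.20. Their adjusted p = 9.45e-05, 1.28e-06 and 0.00202 became adjusted p = 0.0624, 0.111 and 0.223 with an estimated correlation. MuvB subunits, mesoderm, interferon-stimulated, imprinted and proteasome genes were not called (adjusted p = 0.125, 0.0702, 0.727, 0.699 and 0.0851). Of 9 mesoderm genes tested, though, 6 rose and 1 fell (median 1.15). Without Lin52 KO replicate 1 proteasome genes were called (adjusted p = 0.0348). For interferon-stimulated genes the median was -0.22 and the mean 0.49. Within these lists Igf2 rose from 94.7 to 539 CPM, Mybl2 fell (-1.67) and Foxm1 rose (0.81).

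Lin52 KO and F/F differed at 11965 of 16016 genes, 6090 higher and 5875 lower, 4463 of them with an absolute log2 fold change of at least 1. Library totals as the scaling shifted the median of all genes by 0.16 and gave 7260 higher and 4754 lower. Lin52 KO replicate 1 stood apart from replicates 2 and 3 (chi-square per degree of freedom 10.16 and 9, against 2.12 between those), and without it 12386 of 16268 genes tested were called. The mitochondrial share was 2.29 to 2.37% in F/F and at most 1.37% in KO.

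In the Lin37 KO libraries glycolysis and hypoxia genes were called lower, and endoderm and cholesterol synthesis genes higher, but each of these list calls was lost with an estimated correlation (adjusted p = 0.1, 0.168 and 0.107). Among genes with a mean of at least 2 CPM the largest falls were in the imprinted gene Nnat (-3.87, SE 0.11, from 23.1 ± 0.231 to 1.58 ± 0.261 CPM), the autotaxin gene Enpp2 (-3.71), the neurotrophic factor receptor gene Gfra1 (-3.53), the adrenomedullin gene Adm (-3.31), Ndufa4l2 (-3.20) and Bcl11a (-3.03). Elf5, an ETS factor gene of trophoblast stem cells, rose from 0.118 ± 0.072 to 3.93 ± 0.371 CPM (5.04, SE 0.334, adjusted p = 1.16e-08), and the related gene Ehf from 1.19 to 8.57 CPM (2.85). Sh3rf2 (3.15), Pla2g7 (2.91), Capn6 (2.89) and the mesothelin gene Msln (2.87) were the other large rises. Across these 12 genes every KO library lay beyond every F/F library, and the highest adjusted p was 1.63e-07.

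Of 19 glycolysis and hypoxia genes 14 fell in Lin37 KO (17 called adjusted over the list alone, median -0.25), with the hypoxia-inducible genes Egln3 at -2.54, Bnip3 at -1.65 and Ndrg1 at -1.23, while Ldha (0.13) and Hk2 (0.13) rose slightly. Endoderm genes were higher (6 of 13 rose, 7 adjusted over the list alone, median 0.33). Sparc (1.2), Lama1 (1.40), Col4a1 (1.07), Col4a2 (1.05), Lamb1 (0.43) and Pdgfra (1.24) rose and Cubn (-1.257) fell. Most of these encode extracellular matrix proteins. The camera adjusted p = 5.61e-12 and 1.66e-09 became adjusted p = 0.1 and 0.168 with an estimated correlation. Cholesterol synthesis genes rose in 18 of 20 cases (20 adjusted over the list alone, median 0.27; adjusted p = 0.000138, and 0.107 with an estimated correlation), with Pmvk at 0.53, and Hmgcs1 (-0.68) and Insig1 (-0.23) fell. G2/M genes fell in 30 of 55 cases (35 adjusted over the list alone, median -0.12; adjusted p = 6.75e-06, and 0.104 with an estimated correlation), with Cenpa at -0.91 and Ccnf at -0.46, while Anln (0.50), Gtse1 (0.35), Pttg1 (0.16) and Cdc20 (0.09) rose.

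Trophoblast genes were called higher in Lin37 KO through Elf5, Gata3 (1.96), Peg10 (0.84) and Krt8 (0.31), the 4 of 9 that rose (4 adjusted over the list alone; adjusted p = 0.00536, and 0.172 with an estimated correlation). Interferon-stimulated genes were lower (4 of 6, 5 called adjusted over the list alone; adjusted p = 0.0192, and 0.17 with an estimated correlation), among them Bst2 (-0.67), Oasl2 (-2.59) and Ddx58 (-0.18), while Stat2 rose (0.26). Of 11 fibroblast markers 6 fell and no member rose (6 adjusted over the list alone; adjusted p = 0.0366, and 0.172 with an estimated correlation), with Tagln at -0.92 and Acta2 at -1.30. Without Lin37 F/F replicate 1 that call was lost at adjusted p = 0.0528. Imprinted genes were lower as a list (8 of 17 fell, 14 called adjusted over the list alone; adjusted p = 0.0452, and 0.172 with an estimated correlation). Igf2 (1.19), Mest (0.53), Plagl1 (0.62), Zim1 (0.68), H19 (1.41) and Grb10 (0.08) rose. Without Lin37 KO replicate 1 the imprinted call was lost at adjusted p = 0.0605. Amino acid stress genes were lower (8 of 18 fell, 9 called adjusted over the list alone; adjusted p = 0.0198, and 0.302 with an estimated correlation), with Stc2 at -0.89. The lists of MuvB subunits, G1/S, pluripotency, germline, mesoderm, ectoderm, p53 target and proteasome genes were not called (adjusted p = 0.642, 0.646, 0.281, 0.531, 0.99, 0.99, 0.488 and 0.646). The median and mean of MuvB subunits (0.05 and -0.12) differed in sign, as did the median of mesoderm genes (-0.08) and the direction of their test. Within these lists Tdgf1 fell (-1.07), Tfcp2l1 rose (1.30) and Nanog, at -0.07, did not pass the test (adjusted p = 0.06, but 0.00882 with library totals and 0.041 without Lin37 F/F replicate 2, and up to 0.369 in other settings).

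The Lin37 comparison called 7252 of 15954 genes, 3635 higher and 3617 lower, but only 894 with an absolute log2 fold change of at least 1. Library totals as the scaling gave 3079 higher and 4205 lower. The mitochondrial share of counts was higher in KO (3.4 to 3.52%) than in F/F (2.12 to 2.28%).

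In the Lin9 line the imprinted gene Mest was far lower and Igf2 higher, and trophoblast and p53 target genes were higher in KO. Mest (chromosome 6, 30723547 to 30748465) fell from 155 ± 3.08 to 1.59 ± 0.441 CPM (-6.62, SE 0.138, adjusted p = 6.86e-07). Nnat (-4.30), the nucleic acid sensor gene Zbp1 (-3.48), Gfra1 (-3.41), Ripply1 (-2.83) and Nsg2 (-2.82) followed. Among the largest rises were Smtnl1 (3.0, from 1.24 ± 0.234 to 9.92 ± 1.52 CPM), the fructose bisphosphatase gene Fbp2 (2.99) and Gata3 (2.92). Every KO library lay beyond every F/F library for these 9 genes, and the highest adjusted p was 0.000353.

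Of 12 trophoblast genes tested 11 rose in Lin9 KO and Cdx2 did not pass the test (11 called adjusted over the list alone, median 1.51), including Gata3, Peg10 (1.34, from 356 to 903 CPM), Krt18 (1.81) and Krt8 (1.84). Of 23 p53 target genes 17 rose (20 called adjusted over the list alone, median 0.47), such as Plk2 (1.6), Perp (1.47), Mdm2 (0.94) and Apaf1 (0.93), and Gadd45a fell (-0.63). Imprinted genes changed in 16 of 17 cases (16 adjusted over the list alone, median -0.42), with 10 lower and 6 higher. Igf2 (2.86, from 46.6 to 338 CPM), H19 (2.26), Zim1 (1.61), Plagl1 (1.18), Peg3 (0.64) and Igf2r (0.27) rose, and Rian fell (-1.83). Camera gave adjusted p = 7.74e-19, 5.5e-11 and 2.93e-05 for these 3 lists, and with an estimated correlation all 3 held, at adjusted p = 0.0155, 0.0155 and 0.0493.

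Endoderm genes were higher in Lin9 KO (6 of 13 rose, 8 called adjusted over the list alone; adjusted p = 3.12e-06, and 0.21 with an estimated correlation), with Col4a2 at 2.13 and Col4a1 at 1.65. So were fibroblast markers (6 of 11 rose, 7 adjusted over the list alone; adjusted p = 0.00338, and 0.261 with an estimated correlation), with Acta2 at 1.32, Pdgfrb at 1.84 and Dcn at 1.66 while Thy1 fell (-0.52). Glycolysis and hypoxia genes were lower (10 of 19 fell, 12 adjusted over the list alone; adjusted p = 2.93e-05, and 0.331 with an estimated correlation), with Pdk1 at -1.03 and Bnip3 at -1.04. Amino acid stress genes (8 of 18 fell, 8 adjusted over the list alone; adjusted p = 2.93e-05, and 0.261 with an estimated correlation) were also lower, led by Chac1 (-2.43). Cholesterol synthesis genes (8 of 20 fell, 10 adjusted over the list alone; adjusted p = 0.000601, and 0.261 with an estimated correlation) were lower with Insig1 at -0.71. G1/S genes were lower in 12 of 38 cases (15 called adjusted over the list alone; adjusted p = 0.0124, and 0.455 with an estimated correlation), such as Ccne1 (-0.55), while Msh6 (0.22) and Chaf1a (0.21) rose. Of 9 interferon-stimulated genes tested 4 fell, among them Bst2 (-1.09), Oasl2 (-2.37) and Ddx58 (-0.42), and Irf7 (1.98) rose. The Irf7 call was lost with the replicate number as a block (adjusted p = 0.0593), without Lin9 F/F replicate 2 (0.056) and without Lin9 KO replicate 1 (0.0512). The list was called lower (5 adjusted over the list alone; adjusted p = 0.041, and 0.335 with an estimated correlation). That call was lost without Lin9 KO replicate 2 (adjusted p = 0.071) or replicate 3 (adjusted p = 0.0926). The lists of MuvB subunits, G2/M, pluripotency, germline, mesoderm, ectoderm and proteasome genes were not called (adjusted p = 0.441, 0.248, 0.621, 0.11, 0.275, 0.589 and 0.196). Without Lin9 KO replicate 2 germline genes were called higher and proteasome genes lower, each at adjusted p = 0.0288. The MuvB median (0.05) and mean (-0.04) differed in sign. Within these lists Klf4 fell (-1.21), Tbx3 rose (1.66), Nanog rose (0.46) and Hand1 rose (2.57).

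Lin9 KO and F/F differed at 5097 of 15856 genes, 2786 higher and 2311 lower, 1051 of them with an absolute log2 fold change of at least 1. With the replicate number as a block 2966 were called, 1695 higher and 1271 lower. Lin9 KO replicate 2 stood apart from replicates 1 and 3 and leaving it out raised the count to 5974, while 3275 genes were called without Lin9 F/F replicate 3. Genes lower in KO numbered 1528 without Lin9 F/F replicate 2, 1407 without replicate 3, and 3852 when all 24 libraries shared the fit. The mitochondrial share was 1.63 to 2.1% in F/F and 1.76 to 2.52% in KO, lowest in F/F replicate 1 and in KO replicate 2.

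**Figure D2:**
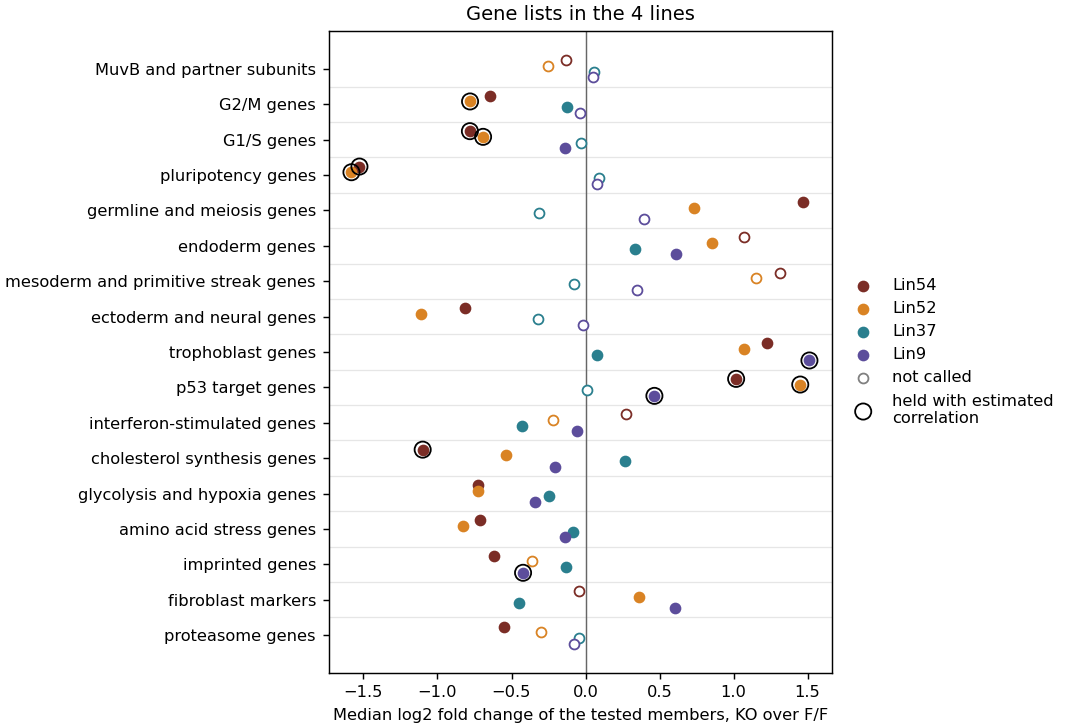
Median log2 fold change (KO over F/F, horizontal axis) of the tested members of 17 gene lists in the 4 lines, with filled points for lists called by camera, open points for lists not called and a black ring where the call held with an estimated correlation. Pluripotency genes lie at -1.53 in Lin54 and -1.58 in Lin52, and trophoblast genes at 1.51 in Lin9.

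Across lines, 1351 genes of 14793 tested in each were called in the same direction in all 4 comparisons, 673 higher and 678 lower, where independent lists would share 86.1 and 87.0. The Lin54 and Lin52 comparisons, the former by labels that Lin54 itself went against, shared most, with 4393 genes higher and 5005 lower in both (independent lists: 2005.2 and 2463.4) and 356 called in opposite directions. Lin37 and Lin9 shared 1463 and 1188 (independent lists: 634.9 and 522.7). Lin54 and Lin37 shared 1314 higher and 1828 lower (independent lists: 1317.4 and 1482.3), with 2749 called in opposite directions (2803.0). The 4 lists are not independent where pairs of lines respond alike. The excess over 86.1 and 87.0 therefore does not by itself show a response common to all 4 lines. The shared genes with the largest mean change were all lower: Zbp1, the interferon-inducible GTPase gene Tgtp1, the keratin gene Krt9, Lefty1, Trh and Nphs1. Lefty1 had log2 fold changes of -4.91, -3.83, -2.36 and -2.19 in the Lin54, Lin52, Lin37 and Lin9 lines. Those of Trh were -4.82, -3.86, -2.22 and -2.42, and those of Nphs1 were -3.96, -5.19, -2.27 and -2.76. Zbp1 went from 139 to 2 summed counts in the Lin54 line (ratio 0.0128, interval 0.00154 to 0.0472), was at least 31.3-fold lower in Lin52 KO against a floor of 3 counts over the group, and was at -2.55 in Lin37 and -3.48 in Lin9. Tgtp1 had a ratio of 0.0251 (interval 0.00298 to 0.094) in the Lin54 line, was at least 16-fold lower in Lin52 KO against the same floor, and was at -3.31 and -2.15 in the Lin37 and Lin9 lines. Krt9 had ratios of 0.0274 (0.00325 to 0.103) and 0.0438 (0.00512 to 0.169) in the Lin54 and Lin52 lines and was at -2.36 in Lin9. Its fall in Lin37 (-1.02, adjusted p = 0.0473) was lost in DESeq2 (adjusted p = 0.151), in the fit of all 24 libraries (0.0613), and without Lin37 F/F replicate 1 (0.143) or 3 (0.15) or KO replicate 1 (0.0977) or 2 (0.185). The strand setting of the counting is not given in the sources used here, so reads of Lin37 and Hspb6, Otx2 and Otx2os1, Mest and Copg2, Nnat and Blcap, Ndufa4l2 and Shmt2, Hspb2 and Cryab, and Nphs1 and Nphs1os, which overlap on opposite strands, may be mixed. Tgtp1, Vmn1r9, H2-M2, Krt8 and Krt18 have near-identical relatives or pseudogenes, and their counts are uncertain to that extent.

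Over these 14793 genes the log2 fold changes of Lin54 and Lin52 correlated at Pearson's r = 0.871 (Spearman's rho 0.865), and those of Lin37 and Lin9 at r = 0.522 (rho 0.457). The other 4 of the 6 pairs gave r = 0.077 (rho 0.049) for Lin54 and Lin37, 0.087 (0.067) for Lin52 and Lin37, 0.262 (0.255) for Lin54 and Lin9 and 0.325 (0.294) for Lin52 and Lin9. These correlations are across genes, which are not independent replicates. With no filter on low counts they were lower, at 0.605 for Lin54 and Lin52 and 0.175 for Lin37 and Lin9, while that of Lin54 and Lin37 became -0.01. Tested directly, the knockout effect differed between lines for 13504 of 17935 genes (omnibus F test of 3 interaction terms, all 24 libraries). The smallest interaction p belonged to Mycn, Nanog, the hypoxia factor gene Epas1, Fgf4, Sfrp1 and Mest. Mycn had log2 fold changes of -4.37 and -4.37 in the Lin54 and Lin52 lines against -0.08 and -0.28 in the Lin37 and Lin9 lines. Its fold change in Lin37 did not pass the test (adjusted p = 0.0513), but did with library totals (0.00956), no filter (0.0267), the replicate block (0.0483), the stricter filter (0.0498) and without Lin37 F/F replicate 2 (0.00174). Epas1 was at -3.61 and -3.76 against 0.67 and -0.41, Fgf4 at -3.24 and -3.60 against 0.45 and 0.40, and Sfrp1 at -2.85 and -2.99 against 0.66 and -0.11. Sfrp1 did not pass in Lin9 (adjusted p = 0.126), but did in the fit of all 24 libraries (0.0075) and without Lin9 KO replicate 2 (0.0407). Line and any batch in which a line was grown or sequenced cannot be told apart. Neither can the likeness of Lin54 and Lin52, or of Lin37 and Lin9, be told apart from a batch that such a pair shared. The F/F libraries paired alike: Lin54 F/F replicate 1 correlated at 0.9859 with Lin52 F/F, against 0.9547 with Lin37 F/F and 0.9652 with Lin9 F/F.

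**Figure D3:**
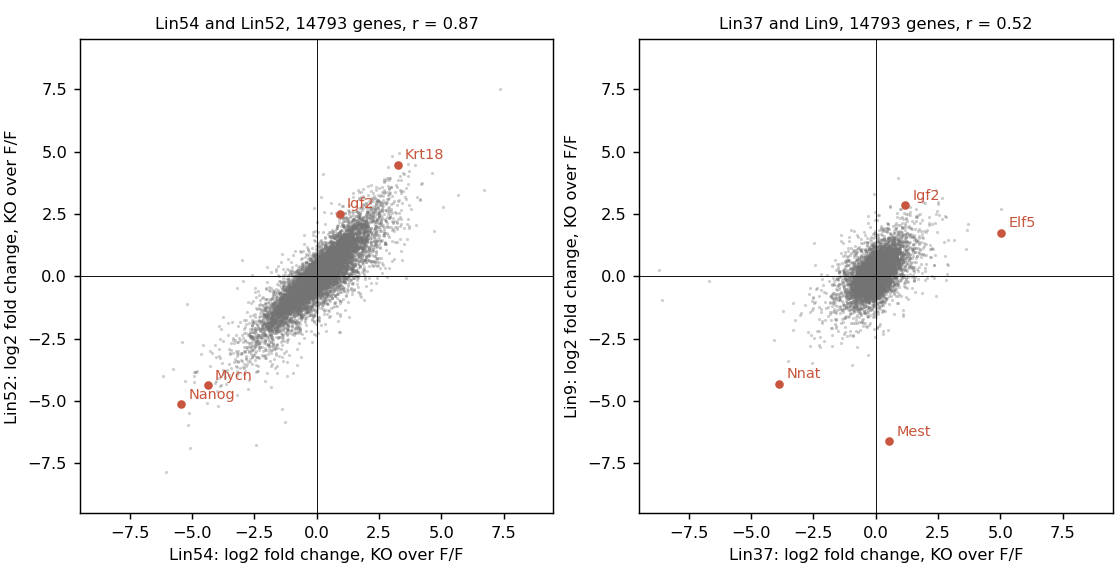
Log2 fold changes of KO over F/F for 14793 genes in the Lin54 (horizontal) and Lin52 (vertical) lines, left, and in the Lin37 (horizontal) and Lin9 (vertical) lines, right, with each point a gene. The left cloud follows the diagonal (r = 0.87) and the right cloud is smaller and rounder (r = 0.52), with Mest far below it.

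**Figure D4:**
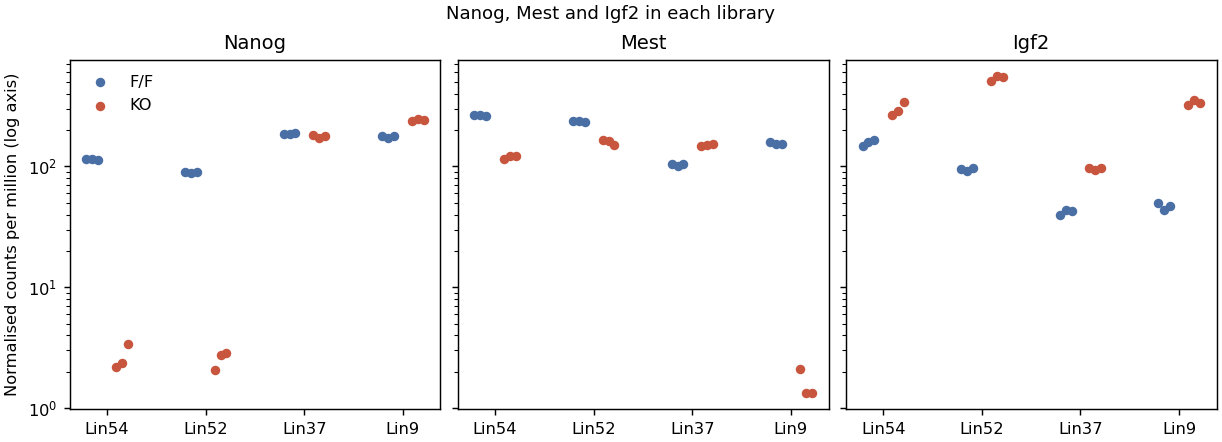
Normalised counts-per-million on a log axis of Nanog, Mest and Igf2 in each of the 24 libraries, grouped by line, with F/F in blue and KO, as labelled, in red. Nanog is near 2.63 and 2.55 in the Lin54 and Lin52 KO groups, and Mest is at a mean of 1.59 in Lin9 KO.

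The two-cell-like genes, which mark a rare state resembling the early embryo, could not be tested as a list because at most 1 of 22 passed the filter in any line. Their summed counts over 3 libraries were 36 in F/F and 89 in the libraries labelled KO in the Lin54 line, 52 and 95 in Lin52, 29 and 26 in Lin37, and 68 and 125 in Lin9. Arg2 alone held 22 of the 36 and 44 of the 89 counts in the Lin54 line and 16 of the 52 and 37 of the 95 in Lin52. It did not pass the test in either line (adjusted p = 0.111 and 0.149), but did without F/F replicate 3 of each line (0.0255 and 0.0285) and, in Lin54, with library totals (0.0438). Most genes of the list belong to multigene families whose reads cannot be assigned with certainty. The authors' deposited table lists an adjusted p under 0.05 for 12556, 11357, 5538 and 4284 genes in the Lin54, Lin52, Lin37 and Lin9 comparisons. Of these, in the authors' deposited table, 5533, 4773, 800 and 949 had an absolute log2 fold change of at least 1.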

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

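The tests of why Lin54 went against its label, of a condition shared with Lin9 F/F replicate 1, and of the imprinted genes were chosen only after the results were seen; those of mixing, GC content and length, and of other splits of the samples were written before, although which of the mixing values decides was chosen after both were seen.

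The effect of KO differed between lines for 13504 genes by the interaction test. Among 40 draws of the F/F and KO labels within lines, 1 gave as many, the real one, and the highest other gave 6915. This meets the share under 0.05 set beforehand against a random grouping of the libraries. Draws that mix F/F and KO libraries widen the spread and lose calls by construction, though, so the comparison decides little. Draws that keep or turn whole lines still hold real differences. For genes called in the same direction in all 4 comparisons, 1 of 100 draws gave as many as the real 1351 and the highest other gave 0, but this decides nothing, since every other split within a line called 0 genes and a draw holding one could share none. Within a line the 10 splits of 6 libraries are too few for a share under 0.05: 1 of 10 gave as many genes as the real split in the Lin54 (13214), Lin52 (11965), Lin37 (7252) and Lin9 (5097) lines, and the highest other called 0 in each by edgeR's quasi-likelihood test. At an unadjusted p under 0.05 the other splits gave at most 36, 52, 190 and 1458 genes, against 13393, 12223, 8317 and 6740 in the real ones.

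Gene lists raised here differed between a pair of lines by camera on the interaction. Each is given for the called pair with the largest median difference in log2 fold change, which need not have the smallest p. Each also held with an estimated correlation between members (adjusted p of 0.0413 or less). Pluripotency genes differed by -1.83 between Lin52 and Lin37 (adjusted p = 1.82e-31), p53 target genes by 1.34 for the same pair (1.25e-13), and ectoderm genes by -0.90 for the same pair (0.0198). Between Lin54 and Lin37, where the Lin54 direction rests on labels that Lin54 itself went against, cholesterol synthesis genes differed by -1.30 (8.06e-19), G1/S genes by -0.68 (6.55e-12) and germline genes by 1.264 (4.17e-05). G2/M genes differed by -0.79 between Lin52 and Lin9 (1.82e-16), and imprinted genes by -0.27 between Lin54 and Lin52 (0.000947). For imprinted genes camera gave a smaller adjusted p for Lin37 minus Lin9 (8.12e-09). There its direction was higher while the median difference was -0.218. Fibroblast markers differed by -1.55 (8.12e-09) and trophoblast genes by -0.88 (5.14e-11) between Lin37 and Lin9.

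Single genes raised here had a tested difference between lines (edgeR's quasi-likelihood test, adjusted p of 0.000147 or less), either called in opposite directions or among the targeted genes and those with the smallest interaction p. Apart from the targeted genes, they were picked by their values in these same libraries. Their small adjusted p therefore restates the choice, and the differences are given as a description. For Lin52 minus Lin37 the difference in log2 fold change was 6.19 for Acta1, -5.71 for Ehf, -4.41 for Epas1, -4.04 for Fgf4, -4.80 for Foxd3, 0.55 for Lin54, -4.27 for Mycn, -3.13 for Pla2g7 and -3.64 for Sfrp1. For Lin54 minus Lin37 it was 6.16 for Adm and -6.01 for Elf5. For Lin54 minus Lin9 it was -5.84 for Nanog and -5.67 for Otx2. For Lin52 minus Lin9 it was 0.83 for Lin9, -6.28 for Neurog1 and -3.92 for Smtnl1, and for Lin37 minus Lin9 it was -1.60 for Lin37 and 7.18 for Mest.

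Lin54 itself was higher in the libraries labelled Lin54 KO. Lin54 had a lowest log2 fold change of 0.34 (SE 0.068) over TMM, DESeq2's size factors and library totals. The choice among these scalings is therefore argued against as the cause. Each is relative to the other counts of a library, so a change in RNA per cell was not tested and stays open. An exchange of labels is argued against, since each Lin54 F/F library correlated better with the F/F than with the KO libraries, by at least 0.019 in the mean over the other 3 lines. That mean rests mostly on Lin52 (for F/F replicate 1, 0.9859 against 0.9314); for Lin9 the difference was small (0.9652 against 0.9617) and for Lin37 slightly the other way (0.9547 against 0.9548). With the F/F libraries of every other line, though, the libraries labelled Lin54 F/F correlated at 0.9547 to 0.9874 and those labelled Lin54 KO at only 0.8841 to 0.9296, where an exchange would need the reverse, if the labels of the other lines are right. Counting over exons outside the deleted part stays open, since the total of 0.34 holds no counts per exon. A response of the gene to the loss of its own protein was not tested.

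Lin9 KO replicate 2 stood apart from replicates 1 and 3 (chi-square per degree of freedom 27.39 and 27.79, against 3.51 between those). Mixing with F/F RNA is argued against: the implied share was 0.007 (95% interval -0.01 to 0.038) over 38 genes lower in KO, below the 0.05 that mixing needed though its upper end passed the bound of 0.02 set against it, while the -0.074 over 45 genes higher in KO was too wide to exclude it alone (-0.149 to 0.082). GC content and gene length explained 0.228 of the variance of its deviation (0.207 to 0.246), under the 0.25 set beforehand, against 0.0089 to 0.126 in the other Lin9 libraries, so they are argued against as the whole cause while part of it goes with them. A condition shared with Lin9 F/F replicate 1 may contribute and stays open (r = 0.347 over genes, 0.218 after removing GC content and length). No biological explanation was tested.

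Imprinted genes changed in both directions in the Lin9 line. A response common to all 4 subunits is open for the list, with 6 of 16 called alike in all 4 lines. Another 4 of 16 were called in opposite directions in different lines (Peg3, Grb10, Zim1 and Mest), so these did not share a direction. These 4 were picked by those same calls, so this describes them and does not test the explanation. Over all genes tested in each line, 1351 of the 4898 called in Lin9 were called alike in all 4 lines. Of the same 4898, 1331 were called in the opposite direction in Lin54 alone. The 6 and 4 of 16 are therefore not shown to be particular to imprinted genes. Fibroblasts are argued against, since Col1a1, Col1a2 and Col3a1 together rose by 0.0182 of the rise of Igf2 (5.30 against 291 counts-per-million). Imprints that differ between the clones or cultures behind each genotype could account for it and cannot be told apart from the loss of Lin9, since the labels give no clones; the mean absolute log2 fold change of the list was 1.61, against 0.31 for matched lists, at percentile 100 of 10000 lists (Lin37 99.9, Lin54 54, Lin52 30). Loss of Lin9 itself stays among the open explanations, as untested.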

How the results depend on the processing

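Library totals as the scaling and the left-out libraries of the correlations were chosen after seeing the data; the other alternatives were planned, and the list tests without Lin9 KO replicate 2 were singled out after seeing the data. Of 383 results on single genes, 352 kept their direction and side of the threshold in every alternative, as did 18 of 68 gene list tests. Of 30 main results 7 stayed within their limits in every alternative (1.5 times for a count, the jackknife error for a correlation, direction and threshold for a targeted gene); the cause of the other moves was not tested, except that a limit on fold change, fewer libraries or more low-count genes act by construction.

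With an absolute log2 fold change of at least 1, calls numbered 5071 (3122 higher, 1949 lower) in Lin54, 4463 (2527, 1936) in Lin52, 894 (432, 462) in Lin37 and 1051 (685, 366) in Lin9. Lists called with an estimated correlation numbered 4, 4, 0 and 3, against 12, 12, 9 and 10. Lists not called in the main test were called with no filter for MuvB subunits in Lin54 (adjusted p = 0.0247) and Lin52 (0.0401), proteasome genes in Lin52 (0.0183) and germline genes in Lin9 (0.0255). Fry, which does not compare a list with other genes, called 17 of the 25 lists not called. In the fit of all 24 libraries 3852 genes were lower in Lin9 KO, against 2311. Leaving out a library gave 3275 (without Lin9 F/F replicate 3) to 5974 (without Lin9 KO replicate 2) calls in Lin9, with 1868 to 3048 higher and 1407 to 2926 lower, and 12880 to 13105 in Lin54, 11304 to 12386 in Lin52 and 6275 to 6786 in Lin37. Lin52 itself was at -0.39 in DESeq2 (adjusted p = 0.0721), -0.24 with library totals (0.154) and -0.50 to -0.25 with a library left out.

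The correlations of fold changes fell where low-count genes entered, in DESeq2 and with no filter: 0.652 and 0.605 for Lin54 and Lin52, 0.123 and 0.109 for Lin54 and Lin9, 0.008 and 0.004 for Lin52 and Lin37, 0.154 and 0.138 for Lin52 and Lin9, and 0.203 and 0.175 for Lin37 and Lin9. That of Lin54 and Lin37 turned to -0.004 and -0.01. With a library left out, that of Lin54 and Lin52 was 0.858 to 0.87 and that of Lin37 and Lin9 0.497 to 0.522.

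The replicate numbers do not pair the libraries: deviations of F/F and KO libraries with the same number correlated at -0.29 to 0.09. With the number as a block, 13080, 11821, 7121 and 2966 genes were called, in Lin9 1695 higher and 1271 lower. The imprinted list in Lin54 was lost under the block (adjusted p = 0.0524) and with library totals (0.0635). In simulation 64% of 1.5-fold changes were recovered in Lin9, against 98, 90 and 96% in Lin54, Lin52 and Lin37.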

Other observations

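The Gene Ontology terms below were tested only after the other results were seen, with camera on terms of 15 to 200 tested genes; the values per library were planned.

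Genes annotated to the cellular response to leukemia inhibitory factor, the cytokine that maintains mouse embryonic stem cells in culture, were lower in the libraries labelled Lin54 KO (86 of 129 fell, adjusted p = 4.74e-11) and in Lin52 KO (93 of 128, 3.23e-14). The adjusted p with an estimated correlation was 0.664 and 0.352. Cellular amino acid biosynthetic process was lower as well, with 22 of 24 genes fallen in each line (adjusted p = 1.48e-09 and 4.64e-09, and adjusted p = 0.664 and 0.732 with an estimated correlation). Cytoplasmic translation was lower in the Lin54 line (48 of 57, adjusted p = 0.000331, and adjusted p = 0.678 with an estimated correlation), while cell-cell junction assembly was higher (26 of 36, 0.0017, and adjusted p = 0.664 with an estimated correlation). In Lin9 KO, integrin-mediated signaling (36 of 98 rose, adjusted p = 0.00993, and 0.884 with an estimated correlation) was higher, and rRNA processing was lower (33 of 154 fell, 0.0263, and adjusted p = 0.906 with an estimated correlation). In Lin37 KO positive regulation of cell-substrate adhesion was higher (18 of 32, 0.00368, and adjusted p = 0.911 with an estimated correlation). Of 1666, 1631, 1577 and 1601 terms tested in the Lin54, Lin52, Lin37 and Lin9 lines, 19, 23, 8 and 53 were called higher and 43, 24, 2 and 1 lower, and 0 held with an estimated correlation. With 6 libraries per line and this many terms, that version of the test could hardly reach the threshold, so the 0 decides little.

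The Y-linked gene Ddx3y lay between 35.59 and 141.8 counts-per-million of the library total in the 8 groups, and Xist between 1.29 and 7.67. In the Lin9 line Ddx3y was at 47.63 in KO replicate 2 against 92.69 and 90.01 in KO replicates 1 and 3, and at 35.59 in F/F replicate 1 against 62.99 and 54.68 in F/F replicates 2 and 3. The fibroblast collagen gene Col1a1 lay between 5.31 and 14.91, and in the Lin9 line at 7.72 to 10.86 in F/F and 12.34 to 14.91 in KO. The median of the fibroblast markers was 1.36 to 2.4 in Lin9 F/F and 2.18 to 4.25 in Lin9 KO.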
